A study of Xenopus laevis with 24 samples.

How the data were processed

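The libraries came from *Xenopus laevis* embryos of 2 clutches exposed in dishes of 25 embryos to TTNPB, AGN193109 or ethanol vehicle, and harvested at stage 10.5 in aliquots of 5 embryos. Per the labels' protocols, total RNA was amplified to cDNA with the NuGEN Ovation V2 kit and sequenced as fragment libraries on an ABI SOLiD sequencer. Per the submitters' processing notes, TopHat, Bowtie and Cufflinks were used, and no version is given there. The genome or transcript set that reads were aligned to is not given in the sources used here. The authors deposited FPKM (fragment counts scaled by transcript length and library size) for 31306 GenBank records in 24 columns, each named for 1 library. Exposure, clutch and replicate were taken from the labels. The labels speak of more replicates per clutch than the 4 per exposure and clutch analysed here. Aliquots of 1 dish may have become several libraries, and the labels do not say which, so p-values measure the spread between aliquots, and the independent sibships are the 2 clutches. FPKM keeps no depth, so no interval that needs counts was computed. No 2 of the 276 library pairs held identical values, and the correlations of log2 values ran from 0.756 to 0.953.

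Records were named in 2 ways. Before any difference between exposures was computed, 246 records were given a gene symbol from their GenBank description. After the first fits had been seen, 2152 of 2547 records described by an NCBI gene number were given the symbol of that number in the RefSeq gene table of assembly Xenopus_laevis_v10.1, and descriptions that name only a family were set aside. This second step changes no count of records past a threshold, but decides which records carry a gene name, among them the second *cyp26a1* record, *sult6b1.5* and *prag1*. Gene list membership rests on the first step alone, and lists enlarged by the second are an added alternative. Records with neither were called by their description where it names a gene.

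Values were transformed to log2(FPKM + 1), and records with a mean of at least 1 FPKM over the 24 libraries were kept (19635). Fold changes are on this scale, which understates the change of low records. Each comparison of exposures was a contrast in 1 limma fit (limma 3.58.1 in R 4.3.3, trended empirical Bayes variance) over all 24 libraries with exposure and clutch as terms, and its SE is the moderated one. The test of a different response between clutches added the interaction of exposure and clutch, and clutch E against clutch D was the clutch term. P-values were adjusted by Benjamini-Hochberg over all tested records with a threshold of 0.05. Gene lists were tested with camera (preset correlation of 0.01), adjusted over the 16 lists within each comparison, with camera under an estimated correlation and fry as alternatives. The lists were the retinoid metabolism and receptor genes, hox paralogs 1 to 5, hox paralogs 6 to 13 with cdx genes, pan-mesodermal, presomitic and organizer genes, ventral and BMP genes, endoderm, neural plate, non-neural ectoderm, FGF feedback, WNT feedback, maternal, early zygotic, cell stress and ribosomal protein genes. The tests were fixed before the data were examined, as were the lists, the alternatives and the rule for naming genes, and later choices are named as such.

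Named genes were, for each comparison of exposures, the 10 largest rises and falls past the threshold with a gene name and the same direction in both clutches, up to 2 rises and 2 falls past the threshold per list, the leading records changed in opposite directions, and a fixed set named whatever their result. Of that set *rarb* had a mean of 0.714 FPKM and was not tested, 1 further gene is not reported here, and *rarg*, *dhrs3*, *aldh1a2*, *wnt8a* and *myf5* were not analysed here, since no record was matched to them by name.

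On data simulated from the real means and spread, with 19635 records, the fit recovered 17 of 100 records changed by log2 0.5 and 69 of 100 changed by log2 1 for TTNPB against vehicle, 23 and 66 of 100 for AGN193109 against vehicle, 19 and 74 of 100 for TTNPB against AGN193109, and 37 and 82 of 100 for the clutches. For records changed in opposite directions it recovered 12 and 56 of 100. Each record was simulated with independent noise of 1 spread for all libraries, while the real AGN193109 replicate 4E stood apart from the others. The recovery in comparisons with AGN193109 therefore need not hold for the real libraries. Overlaps between comparisons that share the vehicle libraries were set beside 100 simulations of unchanged groups and 36 divisions of the vehicle libraries.

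Alternatives were a pseudocount of 0.1 or 0.5, no filter or a mean of at least 5 FPKM, quantile or upper-quartile scaling, only the 2 groups compared, no clutch term, the replicate number as a block, clutch means as replicates, each clutch alone, limma array weights, an adjusted p of 0.01 or an added fold of 1.5, and each library left out in turn. Leaving out the 10 most abundant records and rescaling was added after the data were seen, as were a term for a group of 4 clutch D libraries that stood together and list tests without AGN193109 replicate 4E, under quantile normalization and with the enlarged lists.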

Results

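Transcript levels were measured by RNA sequencing in whole *Xenopus laevis* embryos at gastrula stage 10.5, each library being made from a pool of 5 embryos. Early embryos had been exposed to 1 µM TTNPB, an agonist selective for retinoic acid receptors (RARs), to 1 µM AGN193109, an inverse agonist of the same receptors, or to the 0.1% ethanol vehicle. Each exposure had 8 libraries, 4 from each of 2 clutches (D and E), which made 24 libraries. The deposited values were FPKM for 31306 GenBank transcript records, of which 19635 with a mean of at least 1 FPKM were tested. The values carried no read counts, so the depth of each library is unknown. The median FPKM over the tested records was between 4.23 and 5.76 in 23 libraries and 2.77 in AGN193109 replicate 4E. In that library the 10 most abundant records took 79.2% of all FPKM, against 44.1% to 62.8% in the others. A record is a transcript sequence, so that 1 gene, or its copies on the L and S subgenomes, can be present as several records whose shared reads make the split between them uncertain.

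The comparison of TTNPB with vehicle asked which transcripts an RAR agonist changes before and during early gastrulation. TTNPB raised anterior hox genes and the gene of a retinoid-degrading enzyme. *cyp26a1*, which encodes the enzyme that oxidises retinoic acid, rose from 26.0 ± 6.04 to 239 ± 24.6 FPKM (SD, n = 8 each) in 1 record and from 14.1 ± 3.43 to 127 ± 14.5 FPKM in another, log2 changes of 3.18 ± 0.16 and 3.1 ± 0.15 (SE). *hoxd1*, an early anterior hox gene, rose from 9.90 ± 2.74 to 34.9 ± 5.1 FPKM, a log2 change of 1.75 ± 0.12. *rara*, the gene of RAR alpha, rose from 3.93 ± 1.70 to 12.3 ± 1.52 FPKM, a log2 change of 1.5 ± 0.17. The 4 named records that fell were *hesx1*, the 2 OTX5 records (orthodenticle homolog 5 and OTX5b), which belong to the family of anterior head homeobox genes, and a heparan sulfate 3-O-sulfotransferase.

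All 7 measured records of the hox paralogs 1 to 5 rose, with a median log2 change of 2.24 (camera, adjusted p = 2.37e-71; adjusted p = 2.52e-11 with an estimated correlation), and all 7 passed when adjusted over the list alone. They included *hoxa2* (2.64 ± 0.14), *hoxa3* (2.24 ± 0.11), *hoxb1* (2.22 ± 0.20) and *hoxd1* (1.75 ± 0.12). In the list of hox paralogs 6 to 13 and cdx genes, which act in the posterior trunk, 2 of 4 records rose and 3 passed when adjusted over the list alone (camera, adjusted p = 4.21e-08; adjusted p = 8.69e-04 with an estimated correlation). These were *hoxb6* (1.31 ± 0.17) and *cdx4*, which rose from 20.9 ± 3.18 to 47.1 ± 10.1 FPKM (1.12 ± 0.14). In the list of retinoid metabolism and receptor genes 2 of 7 records rose, *cyp26a1* and *rara*, and the same number passed over the list alone (camera, adjusted p = 2.01e-06; adjusted p = 0.0685 with an estimated correlation). Other genes among the 10 largest rises were a pair of gbx2 records, GBX-2b (2.23 ± 0.21) and Xgbx-2 (2.01 ± 0.16), from a gene expressed behind the midbrain, and a record named transcription factor 2 (2.33 ± 0.23).

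Few genes of the mesoderm and organizer passed the threshold with TTNPB. None of 29 records in the pan-mesodermal and ventrolateral list passed over all records and 1 passed over the list alone (camera, adjusted p = 0.932, with a median of -0.04 and a mean of 0.03). *tbxt* (brachyury), the pan-mesodermal T-box gene, stood at 130 ± 24.4 FPKM with vehicle and 122 ± 21.6 with TTNPB, a log2 difference of -0.09 ± 0.09, and its second record differed by 0.01 ± 0.12. In the presomitic and myogenic list 1 of 18 records rose, also over the list alone, a *mespa* record known as thylacine 2 (0.85 ± 0.20, adjusted p = 0.030; camera, adjusted p = 0.011; adjusted p = 0.23 with an estimated correlation). That call was lost when any 1 of 13 of the 24 libraries was left out, with adjusted p up to 0.0916, and with a pseudocount of 0.1 (0.0599). The other *mespa* records differed by -0.11 ± 0.17 and -0.10 ± 0.17, *msgn1* by 0.23 ± 0.22, *tbx6* by 0.19 ± 0.16 and the *myod1* records by 0.21 ± 0.17 and 0.18 ± 0.18, none past the threshold. The organizer and axial mesoderm list was lower as a set with a median of -0.32 (camera, adjusted p = 3.23e-06; adjusted p = 0.108 with an estimated correlation), but 15 of its 17 records did not pass. In it *hesx1*, a repressor gene expressed in the anterior neural plate, fell by 1.00 ± 0.21. *lhx1*, a LIM homeobox gene of the organizer, rose by 0.91 ± 0.17, while *gsc* stood at -0.64 ± 0.32 and *chrd* at -0.17 ± 0.17. Over that list alone 3 records were lower and 1 was higher.

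Genes of the ectoderm and of FGF and WNT feedback were among the other risers. In the non-neural ectoderm list 2 of 16 records rose, *dlx3* (0.98 ± 0.19) and *foxi1* (0.94 ± 0.15), and 6 rose when adjusted over the list alone (camera, adjusted p = 5.14e-06; adjusted p = 0.12 with an estimated correlation). Of 7 FGF feedback records 1 rose, a record of *dusp6*, the phosphatase that inactivates ERK (1.34 ± 0.18), and 3 over the list alone (camera, adjusted p = 3.67e-05, and 0.0705 with an estimated correlation). A second *dusp6* record, named by gene number and outside the list and the naming rule, rose by 1.12 ± 0.12 (limma, adjusted p = 6.55e-07). Of 11 WNT feedback records 2 rose, also over the list alone, *fzd10* (0.95 ± 0.18) and *dact1* (0.69 ± 0.16), the latter with an adjusted p between 0.0530 and 0.0785 when 1 of 10 libraries was left out (camera, adjusted p = 0.00751; adjusted p = 0.301 with an estimated correlation). No record passed in the ventral and BMP list of 22 (3 over the list alone; camera, adjusted p = 0.00751; adjusted p = 0.446 with an estimated correlation) or in the cell stress list of 6 (3 over the list alone; camera, adjusted p = 0.00317; adjusted p = 0.12 with an estimated correlation). The same was true of the early zygotic list of 6, with a median of -0.30 (camera, adjusted p = 0.00751; adjusted p = 0.193 with an estimated correlation), and of the maternal list of 20, with a median of -0.10 (camera, adjusted p = 0.0462; adjusted p = 0.621 with an estimated correlation). The neural plate list (20 records, 2 over the list alone, adjusted p = 0.145), the endoderm list (12 records, adjusted p = 0.973) and the ribosomal protein list (15 records, adjusted p = 0.671, median 0.02 and mean -0.02) did not pass with camera.

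In all, 163 of 19635 records passed the threshold for TTNPB against vehicle (limma, Benjamini-Hochberg adjusted p under 0.05), 154 higher and 9 lower, and all 163 differed in the same direction in both clutches. Of these, 77 differed by at least 2-fold. Without AGN193109 replicate 4E, whose spread enters the shared error of the fit, 300 records passed, 260 higher and 40 lower. With the clutch means as replicates (2 per exposure) 26 passed, all higher. Of the genes named above *hesx1*, OTX5b, the heparan sulfate 3-O-sulfotransferase, *lhx1*, *dlx3*, *foxi1* and thylacine 2 passed neither with clutch means nor in either clutch alone. Clutch means also ended the calls of *rara* (limma, adjusted p = 0.272), *cdx4* (0.194), *hoxb6* (0.0903), orthodenticle homolog 5 (0.484), *fzd10* (0.606) and *dact1* (0.492). Clutch D alone ended those of *cdx4*, *hoxb6*, orthodenticle homolog 5, the *dusp6* record of the FGF list and *fzd10*, and clutch E alone that of *dact1*. The calls of *cyp26a1*, *hoxd1*, *hoxa2*, *hoxa3*, *hoxb1*, the gbx2 records and transcription factor 2 were kept in all of these fits.

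**Figure D1:**
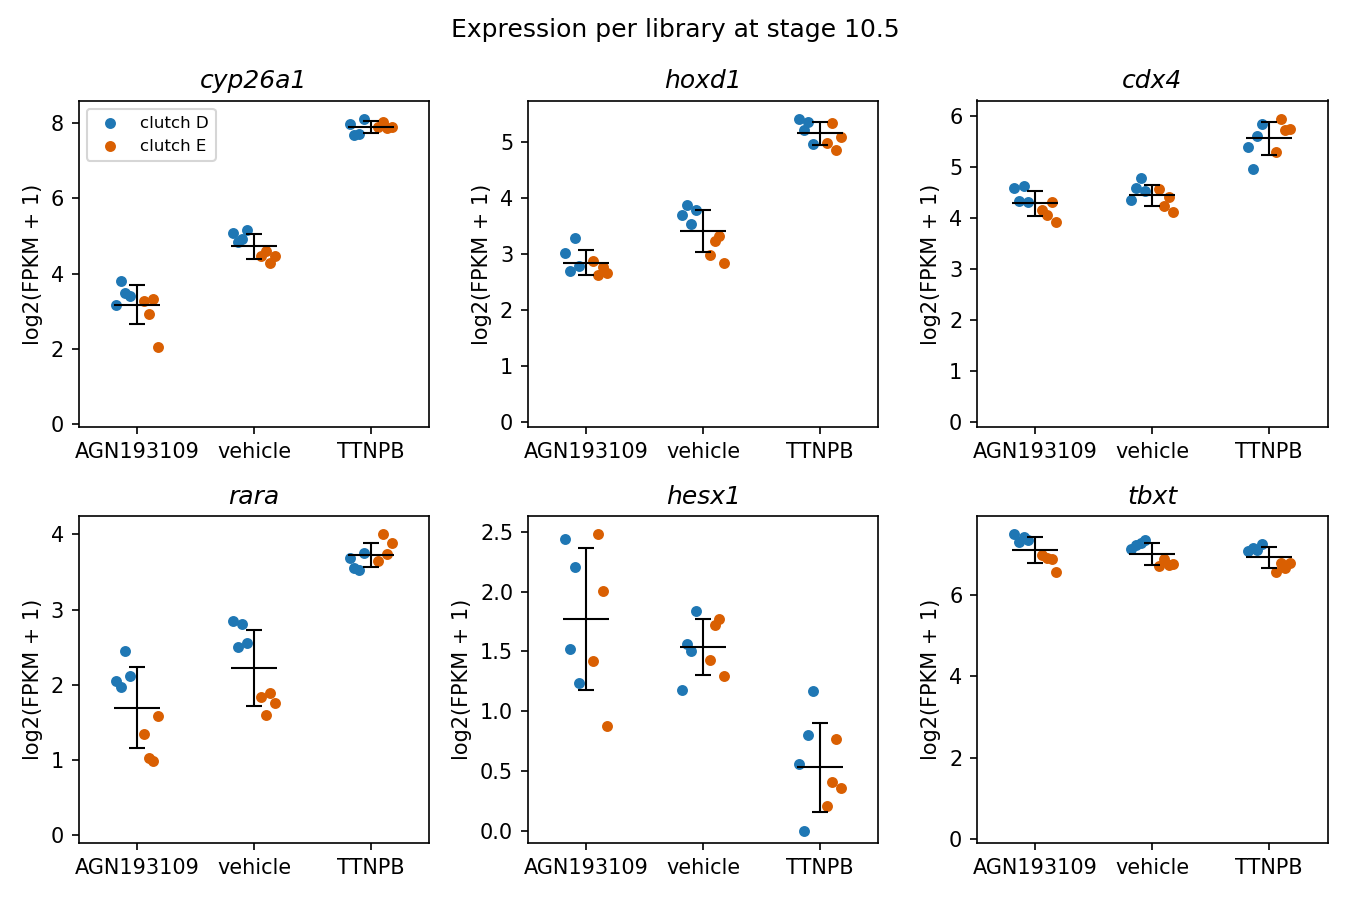
Expression of 6 genes in each of the 24 libraries, as log2(FPKM + 1), by exposure; points are libraries coloured by clutch, and the bars give the mean and SD over 8 libraries. All TTNPB libraries lie above all vehicle libraries for *cyp26a1*, *hoxd1*, *cdx4* and *rara*, and below all vehicle libraries for *hesx1*, while the exposures overlap for *tbxt*.

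The comparison of AGN193109 with vehicle asked which transcripts depend on receptor activity present without added agonist. AGN193109 lowered *cyp26a1* in both records, from 26.0 ± 6.04 to 8.48 ± 2.84 FPKM and from 14.1 ± 3.43 to 3.11 ± 1.38 FPKM (SD, n = 8 each), log2 changes of -1.55 ± 0.16 and -1.93 ± 0.15 (limma, adjusted p = 7.06e-06 and 8.08e-08). In all 8 AGN193109 libraries both records lay below the vehicle mean of their clutch. The first record did not pass in clutch E alone (log2 change -1.56, adjusted p = 0.201), and with clutch means as replicates neither did (adjusted p = 0.341 and 0.339, with the same log2 changes). *sult6b1.5*, a gene of the sulfotransferase family, rose from 1.53 ± 0.55 to 3.27 ± 0.45 FPKM (0.78 ± 0.12, adjusted p = 0.00787). That call was lost with a pseudocount of 0.1 (adjusted p = 0.0685), with only the 2 groups compared (0.0835), with no clutch term (0.0777), with clutch means as replicates (0.744) and in clutch D (0.324) or clutch E (0.525) alone. The remaining record past the threshold, an unnamed complementary DNA clone singled out after its values were seen, stood at -0.96 (adjusted p = 0.0287).

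The hox paralogs 1 to 5 were lower with AGN193109 as a set (camera, adjusted p = 4.47e-05; adjusted p = 0.0119 with an estimated correlation), with a median log2 change of -0.46. In clutch D alone the list passed (adjusted p = 1.22e-05) and in clutch E alone it did not (adjusted p = 0.12), and the difference between the clutches was not tested for the list. None of the 7 records passed over all records and 4 passed when adjusted over the list alone. *hoxd1* stood at 9.90 ± 2.74 FPKM with vehicle and 6.25 ± 1.2 with AGN193109, a log2 difference of -0.56 ± 0.12 (adjusted p = 0.121), and lay below the clutch mean of vehicle in 8 of 8 libraries. *rara* differed by -0.53 ± 0.17 (adjusted p = 0.36). In the retinoid list of 7 records *cyp26a1* was the 1 that fell and 2 were lower when adjusted over the list alone (camera, lower, adjusted p = 0.109, although the median was 0.02). Among 29 pan-mesodermal, 18 presomitic and 17 organizer records none passed, over all records or over the list alone (camera, adjusted p = 0.529, 0.529 and 0.703). *tbxt* differed by 0.10 ± 0.09 and 0.05 ± 0.12, *msgn1* by 0.06 ± 0.22, *tbx6* by 0.12 ± 0.16, *myod1* by 0.14 ± 0.17 and -0.13 ± 0.18, the *mespa* records by -0.08 ± 0.17, 0.10 ± 0.17 and 0.07 ± 0.20, *cdx4* by -0.15 ± 0.14, *gsc* by -0.56 ± 0.32 and *chrd* by -0.08 ± 0.17. In AGN193109 replicate 4E *chrd* stood at 20.9 FPKM against 58.9 to 80.8 in the other libraries of that exposure, and *tbx6* at 9.90 against 19.3 to 25.7. Without that library *gsc* differed by -0.25 and *chrd* by 0.11, neither past the threshold. *rdh10*, which encodes a retinol dehydrogenase of retinoic acid synthesis, differed by 0.19 ± 0.15, and by -0.07 ± 0.15 with TTNPB. The closest of the other lists were the early zygotic genes and the ribosomal proteins, both lower (camera, adjusted p = 0.0564 for each), and no record of either passed. For the hox paralogs 6 to 13 and cdx genes, the ventral and BMP, endoderm, neural plate, FGF, WNT, maternal and cell stress lists the adjusted p with camera lay between 0.319 and 0.837 with no record past the threshold, also over the list alone. The non-neural ectoderm list had 1 record lower over the list alone (camera, adjusted p = 0.529). The median and the mean had opposite signs for the WNT (-0.04 and 0.07), ventral and BMP, endoderm and cell stress lists.

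For AGN193109, 4 records passed (limma, adjusted p under 0.05), 1 higher and 3 lower. At an unadjusted p under 0.05 there were 1633, and 1158 for TTNPB against vehicle. A share of 0.05 of the 19635 records is expected there without any change, so these counts do not measure the size of a response. Without AGN193109 replicate 4E 16 records passed, 10 higher and 6 lower, without vehicle replicate 4D 7 passed, and with the clutch means as replicates none passed (limma). With quantile normalization 6 passed, 3 of them higher, and with upper-quartile scaling 5, of which 3 were higher.

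**Figure D2:**
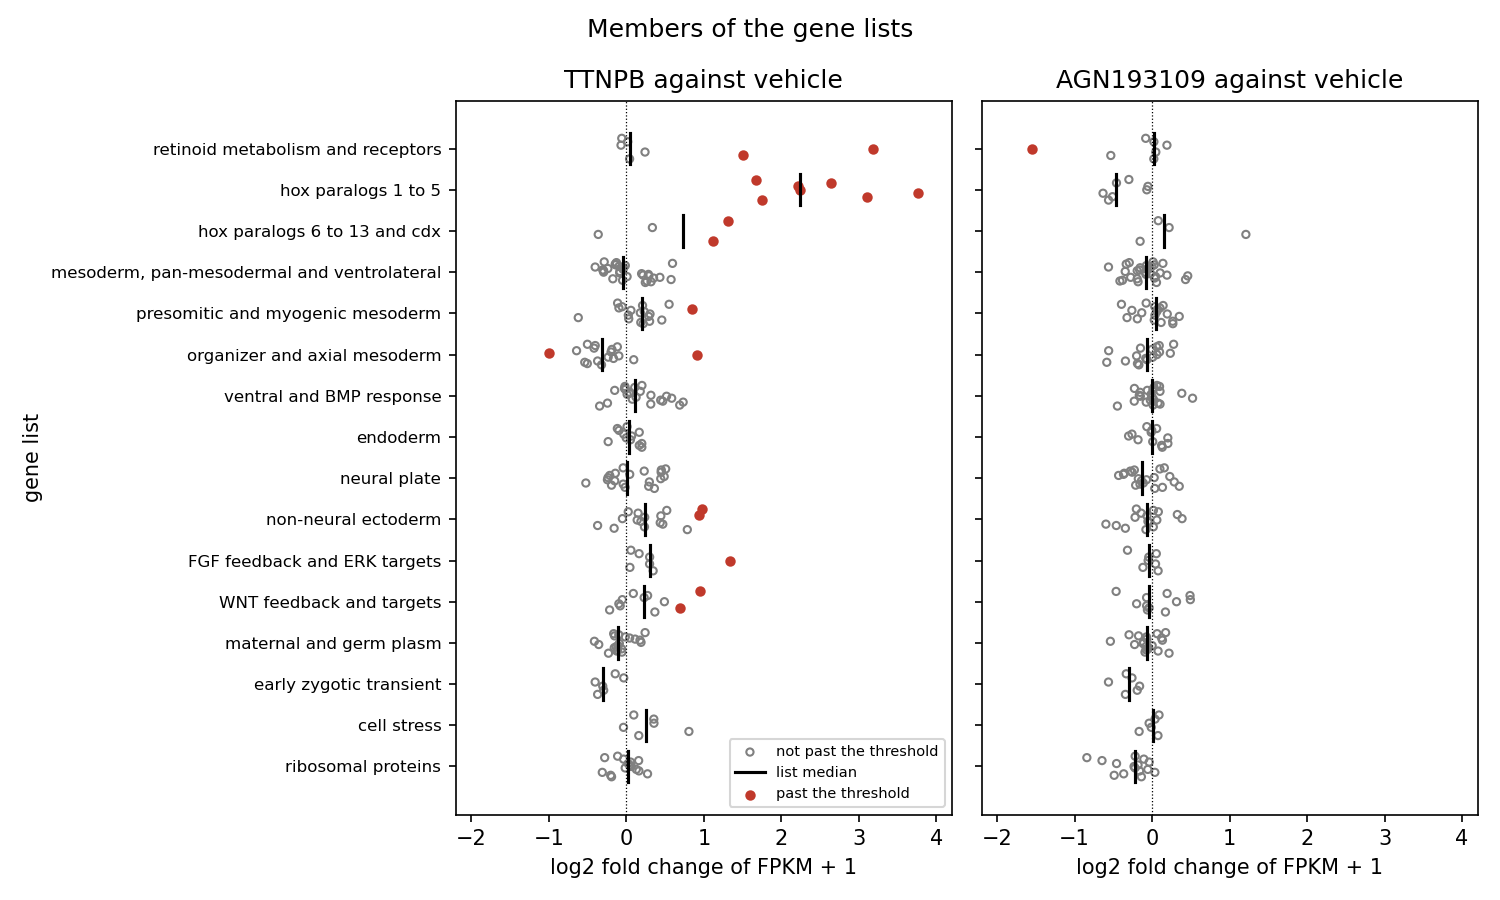
Log2 fold changes of FPKM + 1 for the members of the 16 gene lists, 1 point per record, for TTNPB (left) and AGN193109 (right) against vehicle; filled points passed an adjusted p of 0.05 over all records and vertical bars are list medians. The 7 records of hox paralogs 1 to 5 all lie above 1 with TTNPB and have a median of -0.46 with AGN193109.

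TTNPB and AGN193109 were also compared directly at the same dose, a contrast in which no vehicle library enters the difference. The *cyp26a1* records were higher with TTNPB by log2 5.03 ± 0.15 and 4.73 ± 0.16 (32.6-fold and 26.5-fold on the scale of FPKM + 1). Also among the 10 largest rises were *hoxa2* (3.1 ± 0.14), transcription factor 2 (2.87 ± 0.23), B2 keratin (2.86 ± 0.26), the nuclear orphan receptor xGCNF (2.56 ± 0.22), a record described as a zinc finger protein (2.55 ± 0.26) and GBX-2b (2.49 ± 0.21). Lower with TTNPB were *hesx1* (-1.24 ± 0.21), *sult6b1.5* (-1.11 ± 0.12), orthodenticle homolog 5 (-1.08 ± 0.11), OTX5b (-0.72 ± 0.10) and XAG (-0.86 ± 0.18), a secreted protein of the cement gland. A HES-related record, XHR1-B (-0.78 ± 0.15), superficial protein 1 (-0.62 ± 0.10) and *prag1* (-0.50 ± 0.11) were also lower. With clutch means as replicates none of these 8 falls passed, and of them only *sult6b1.5* and orthodenticle homolog 5 passed in each clutch alone, with OTX5b passing in clutch D. The call of *prag1* was also lost without TTNPB replicate 3E (adjusted p = 0.0537) and with only the 2 groups compared (0.0762), and that of XAG with no clutch term (0.0720).

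All 7 records of hox paralogs 1 to 5 were higher with TTNPB (camera, adjusted p = 1.18e-63; adjusted p = 7.36e-11 with an estimated correlation), *hoxd1* by 2.31 ± 0.12, and the 7 also passed when adjusted over the list alone. So were 2 of 7 retinoid records, *cyp26a1* and *rara* (2.03 ± 0.17) (camera, adjusted p = 2.51e-05; adjusted p = 0.0923 with an estimated correlation), and 2 of 4 in the list of hox paralogs 6 to 13 and cdx genes, *cdx4* (1.27 ± 0.14) and *hoxb6* (1.23 ± 0.17) (camera, adjusted p = 6.93e-04; adjusted p = 0.0563 with an estimated correlation). In the non-neural ectoderm list 4 of 16 were higher, among them *dlx3* (1.18 ± 0.19) and *foxi4.2* (1.07 ± 0.17) (camera, adjusted p = 8.16e-07; adjusted p = 0.104 with an estimated correlation). In the FGF list 1 of 7 was higher, *dusp6* (1.39 ± 0.18) (camera, adjusted p = 1.28e-04; adjusted p = 0.0923 with an estimated correlation), and in the cell stress list 1 of 6, *gadd45g* (0.97 ± 0.23), a call that 8 of 24 leave-outs, no filter, only the 2 groups, no clutch term and the replicate block ended, the last with an adjusted p of 0.0537, and which differed by 0.25 in clutch D alone (adjusted p = 0.779) and passed in clutch E alone (camera, adjusted p = 0.0199; adjusted p = 0.243 with an estimated correlation). The organizer list was lower as a set (camera, adjusted p = 6.72e-04; adjusted p = 0.243 with an estimated correlation), with *hesx1* lower and *lhx1* higher (0.85 ± 0.17). When adjusted over the list alone, 2 retinoid, 6 non-neural ectoderm, 2 FGF and 2 cell stress records were higher, 2 of the hox paralogs 6 to 13 and cdx genes were higher and 1 was lower, and 1 organizer record was higher and 3 were lower.

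Among mesodermal genes 1 of 29 pan-mesodermal records passed in this contrast, *fgf20*, an FGF ligand, at 1.76 ± 0.25 FPKM with TTNPB against 0.69 ± 0.17 with AGN193109 (0.71 ± 0.11). *tbxt* was lower with TTNPB by a log2 difference of -0.19 ± 0.09, which did not pass (adjusted p = 0.587). The difference was -0.24 and passed without AGN193109 replicate 4E (adjusted p = 0.0138), and with limma array weights, which gave that library a weight of 0.0474, it was -0.23 (adjusted p = 0.0153). The *mespa* record thylacine 2 differed by 0.78 ± 0.20 (adjusted p = 0.0505), and passed when any 1 of 5 libraries was left out and under quantile and upper-quartile scaling. In the WNT list 2 of 11 records were higher, *fzd10* (1.42 ± 0.18) and *dact1* (0.73 ± 0.16, lost with only the 2 groups at an adjusted p of 0.0826), with camera at an adjusted p of 0.105. In the ventral and BMP and neural plate lists 1 record each was higher, *id2* (0.67 ± 0.16) and *neurog2* (0.68 ± 0.16), calls that 7 and 11 of the 24 leave-outs ended, as did only the 2 groups compared and no clutch term (camera, adjusted p = 0.0584 for both lists). The pan-mesodermal, presomitic, endoderm, maternal, early zygotic and ribosomal lists did not pass with camera (adjusted p = 0.284, 0.249, 0.599, 0.249, 0.936 and 0.0584). The endoderm and early zygotic tests pointed lower although their medians were 0.06 and 0.07, and the maternal list had a median of 0.01 and a mean of -0.02. When adjusted over the list alone, 2 pan-mesodermal, 2 presomitic, 4 ventral and BMP, 3 neural plate and 3 WNT records were higher.

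In this contrast 212 records passed, 192 higher with TTNPB and 20 lower (limma, adjusted p under 0.05), all 212 with the same direction in both clutches. With quantile normalization 285 passed, 80.4% of them higher, against 90.6% of the 212. There were 294, 71.4% of them higher, without AGN193109 replicate 4E, and with the clutch means as replicates 46 passed. The rises of *lhx1*, *foxi4.2*, *fgf20*, *id2*, *neurog2* and *dact1* passed neither with clutch means nor in either clutch alone. Clutch means also ended the calls of *rara* (limma, adjusted p = 0.0730), *cdx4* (0.0949), *hoxb6* (0.0803), *dlx3* (0.247), *fzd10* (0.167) and *gadd45g* (0.716). Clutch D alone ended those of *hoxb6*, *dlx3*, the *dusp6* record of the FGF list and *gadd45g*. The other rises named for this contrast, among them *cyp26a1*, *hoxa2* and *hoxd1*, were kept in all of these fits.

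Records changed in opposite directions by the agonist and the inverse agonist were counted next, since the 2 compounds act on the same receptors. Both *cyp26a1* records were higher with TTNPB and lower with AGN193109 than with vehicle, and so was the unnamed clone record. These 3 records made up the whole set, and none passed in both comparisons with the same direction. Independent lists of these sizes would share 0.0240 records in opposite directions, and 100 simulations of unchanged groups against the same vehicle libraries gave 0. With unchanged groups few records can pass in either comparison, so that 0 was nearly fixed beforehand and decides nothing. With the vehicle libraries divided between the comparisons, the 36 divisions gave a median of 2 such records (2 to 3). Across records, which are not independent replicates, the log2 changes of the 2 comparisons correlated at r = 0.385 against a simulated 0.487. Their covariance was 0.0261 against a simulated 0.0264, a difference of -2.37e-04. The simulations dealt the deviations of all libraries of a clutch, AGN193109 replicate 4E included, to any group. The simulated correlation and covariance therefore need not equal the part from the shared vehicle libraries, and no conclusion is drawn from them. With the vehicle libraries divided the median covariance was 0.00543 and the median correlation 0.0613. Without AGN193109 replicate 2E there were 5 such records, and in clutch E alone 1.

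The clutches were compared for their response to each compound. *cyp26a1* rose with TTNPB by log2 2.88 in clutch D and 3.48 in clutch E in 1 record, and by 2.94 and 3.26 in the other. *hoxd1* rose by 1.52 and 1.98, and *rara* by 0.95 and 2.05, a difference of 1.09 ± 0.22 that had the smallest adjusted p for TTNPB but did not pass (limma, adjusted p = 0.198). With AGN193109 the *cyp26a1* records differed by -1.54 and -1.59 in clutch D and by -1.56 and -2.28 in clutch E. *gsc* differed by 0.21 in clutch D and -1.34 in clutch E with AGN193109, a difference between clutches of -1.55 ± 0.59 that did not pass (limma, adjusted p = 0.798). Over both clutches its AGN193109 difference of -0.56 was -0.25 without AGN193109 replicate 4E. No record passed the test of a different response between clutches, for TTNPB (limma, 0 records) or AGN193109 (limma, 0 records). At an unadjusted p under 0.05 there were 509 for TTNPB and 1115 for AGN193109, the latter with a median over all records of -0.15. A share of 0.05 of the 19635 records is expected there without any difference. On simulated data this test recovered 17 of 100 TTNPB differences of log2 1 and 62 of 100 of log2 2, so that smaller differences could be missed. Without TTNPB replicate 4D 3 records passed for TTNPB.

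Clutch E was set against clutch D over all exposures to size the difference between these sets of libraries. A difference between sibships cannot be told apart there from one in handling, exact stage or library preparation. The named list members below were chosen after their values were seen, as those with the largest differences called in the same direction with and without quantile normalization. *szl* (sizzled), a secreted feedback inhibitor of the BMP pathway expressed ventrally, was lower in clutch E in both records, from 8.49 ± 2.06 to 1.77 ± 0.89 FPKM and from 12.9 ± 3.51 to 4.2 ± 1.55 FPKM (SD, n = 12 each), log2 differences of -1.82 ± 0.16 and -1.43 ± 0.16. A *tp63* record, an epidermal transcription factor gene, was lower at -1.41 ± 0.33, 1 of the 2 *wnt5a* records at -1.29 ± 0.33 (2.82 ± 3.0 FPKM in clutch D and 0.272 ± 0.543 in clutch E, the other record differing by -0.09) and *zpc*, a maternal egg coat gene, at -1.25 ± 0.14. Higher in clutch E were *nodal3.2* (0.74 ± 0.20) and *sia1* (0.47 ± 0.15), both induced early in the organizer region, *gdf1* (Vg1, 0.63 ± 0.11), a maternal TGF-beta ligand, and the neural plate genes *irx1* (0.53 ± 0.16) and *foxd4l1.2* (0.48 ± 0.14). In the ventral and BMP list 13 of 22 records were lower and 1 was higher, and with quantile normalization 9 were lower and 1 was higher. In the neural plate list 4 of 20 were higher and 1 was lower, against 9 higher and none lower with quantile normalization.

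In total 6256 records differed between the clutches (limma, adjusted p under 0.05), 732 higher and 5524 lower in clutch E. The median over all records was a log2 difference of -0.20, and single differences are to be read against that shift. Under quantile normalization 5400 passed, 2586 higher and 2814 lower, and under upper-quartile scaling 5442, of which 2521 were higher and 2921 lower.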

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

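The tests of the patterns below were written before the values they measure were computed, but after the main counts and the library measures, among them those of AGN193109 replicate 4E, had been seen. Within each exposure a library was marked where its gap to the nearest of the other 7 exceeded Dixon's limit for 8 values, which chance exceeds in about 1 of 20 groups. Of 15 groups of library measures 4 held such a library, and in each it was AGN193109 replicate 4E. Its median FPKM over the tested records was 2.77 (others 4.97 to 5.73), it had 16236 records at 1 FPKM or more (others 18671 to 19535), its 10 most abundant records took 79.2% of FPKM (others 44.1% to 57.8%), and its mean correlation with the libraries of its clutch and exposure was 0.788 (others 0.888 to 0.937).

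Of 141 groups of named-gene values 13 held a library apart, 9.22% of them. In AGN193109 replicate 4E *chrd* was at 20.9 FPKM (others 58.9 to 80.8), *dact1* at 12.7 (27.6 to 36.3) and *tbx6* at 9.90 (19.3 to 25.7). The other AGN193109 library apart was replicate 1D for *hoxb6* at 1.45 FPKM. Among the TTNPB libraries replicate 3D stood apart for the *mespa* record thylacine 1 at 2.44 FPKM and replicate 2E for a *cyp26a1* record at 160 FPKM. Among the vehicle libraries they were replicate 3D for *cyp26a1* at 22 FPKM and Xgbx-2 at 5.33 FPKM, replicate 1D for transcription factor 2 at 4.61 FPKM and GBX-2b at 2.88 FPKM, replicate 2D for *hoxb1* at 1.68 FPKM, replicate 2E for XAG at 9.98 FPKM and replicate 3E for the zinc finger protein record at 47.4 FPKM.

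Few records passed for AGN193109 against vehicle, and an aberrant library and a response weaker than that to TTNPB were weighed. Without AGN193109 replicate 4E 16 records passed in place of 4. Leaving out vehicle replicate 4D also moved it, to 7, so the test set for a single library as the whole cause was not met. Clutch D alone, which does not hold AGN193109 replicate 4E, gave 4 records for AGN193109 and 48 for TTNPB (limma). These counts, and 16 against 300 without that library, argue against it as the whole cause. A part played by it stays open. In the fit without replicate 4E TTNPB had 300 records past the threshold, and over those, which were chosen for their TTNPB change, the median size of the change was 0.18 with AGN193109 and 0.74 with TTNPB. A response at this dose and stage smaller than that to the agonist may account for part of the gap between 16 and 300. The choice of records by their TTNPB change favours TTNPB, however. Some of them, such as *hoxb1* and *hoxa3*, had a mean below 1 FPKM with vehicle. On the scale of log2(FPKM + 1) such records can fall only a little. Part of the smaller AGN193109 change may come from that floor, and how many of the 300 records it concerns was not counted. Differences in potency or uptake were not tested.

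Most of the records that differed between the clutches were lower in clutch E. Under quantile normalization 52.1% of the called records were lower, but equal distributions pull that share toward an even balance whatever the cause, so the scaling of FPKM between libraries cannot be told apart from a broad shift in the embryos. Without the 10 most abundant records and after rescaling 68.8% were lower, between the limits set for and against a few dominant records, so their part cannot be told apart from that of a wider shift. A biological difference between the sibships, such as in maternal RNA, stays open for the records called under both scalings and was not tested. It cannot be told apart from a difference between the clutches in handling, exact stage or library preparation.

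With other splits of the libraries chance in how aliquots fell into groups could be excluded for 4 counts, those of the 3 comparisons of exposures and of the clutches. The splits exchange aliquots, which may share a dish, so chance between dishes or sibships is not covered, and with clutch means as replicates 0 records passed for AGN193109 and 0 in opposite directions. In 1 of 100 splits, the real split, as many records passed as were found for TTNPB against vehicle (163; highest other 27), AGN193109 against vehicle (4; highest other 1), TTNPB against AGN193109 (212; highest other 7), opposite directions (3; highest other 0) and the clutches (6256; highest other 2). Permuting the exposures also removes the TTNPB response, so the 0 for opposite directions was nearly fixed beforehand. It decides nothing about chance in that overlap. For the response to either compound between clutches the real count was 0, which each of the 100 regroupings reaches by construction, so nothing follows about chance (highest other 1 for TTNPB and 3 for AGN193109).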

How the results depend on the processing

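The removal of the 10 most abundant records, the enlarged lists and the term for a group of clutch D libraries were chosen after the data were seen. No named gene past the threshold in either fit had the opposite sign in the other, and no list past it in both fits did. The balance of AGN193109 records turned from 1 higher and 3 lower to 10 higher and 6 lower without AGN193109 replicate 4E. Among the 6256 records that differed between the clutches, 3540 were still called under quantile normalization and 3653 under upper-quartile scaling, while 6242 and 6241 kept their sign. Some estimates that did not pass crossed 0 on leave-outs, such as *chrd* with AGN193109 (-0.15 to 0.11). Of the 56 named-gene results past the threshold 6 were lost when at least 1 library was left out, 0 under another scaling, 6 with only the 2 groups compared, 28 in clutch D alone, 22 in clutch E alone and 36 with clutch means as replicates, where each exposure has 2 values. Depth is unknown here, so its limit was not assessed. Replicate numbers did not pair libraries: of 24 same-numbered pairs 1 had deviations correlated above 0.1 (mean -0.00276), and 6 of 24 libraries correlated best with their own number. With a term for 4 clutch D libraries that stood together (vehicle replicate 3D, TTNPB replicate 4D and AGN193109 replicates 2D and 4D) 7 records passed for AGN193109, 4 of them higher, the other record counts stayed within 1.5-fold and no named-gene call changed. With the replicate number as a block 144 records passed for TTNPB against vehicle, 3 for AGN193109, 191 for TTNPB against AGN193109 and 2 in opposite directions, with 0 for each response between clutches. Under that block the lists past the threshold were 12, 1 and 10, and of the named genes 1 call was lost.

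The causes of the following changes were not tested, except that clutch means and single clutches leave fewer samples, a stricter filter fewer records and a stricter threshold fewer calls. For TTNPB against vehicle (163) the count was 86 at a mean of at least 5 FPKM, 275 with only the 2 groups, 26 with clutch means, 48 in clutch D, 63 in clutch E, 362 with array weights, 101 at an adjusted p of 0.01, and 131 to 300 when 1 library was left out, the highest without AGN193109 replicate 4E. For AGN193109 (4) it was 2 with a pseudocount of 0.1, 2 with only the 2 groups, 2 with no clutch term, 0 with clutch means, 1 in clutch E, 15 with array weights, and 3 to 16 when 1 library was left out, with 16 without AGN193109 replicate 4E and 7 without vehicle replicate 4D. For TTNPB against AGN193109 (212) it was 121 at a mean of at least 5 FPKM, 46 with clutch means, 79 in clutch D, 119 in clutch E and 346 with array weights, of which 241 were higher. Leave-outs gave 184 to 294. For opposite directions (3) it was 0 with clutch means, 1 in clutch E and 2 to 5 over the leave-outs, with 5 without AGN193109 replicate 2E. With no filter 2 records passed for each response between clutches, and leave-outs gave 0 to 3 for TTNPB (3 without TTNPB replicate 4D). For the clutches (6256) it was 3745 at a mean of at least 5 FPKM, 3351 with clutch means, 3932 at an adjusted p of 0.01, 2742 with a fold of 1.5 and 5680 to 7774 over the leave-outs.

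Gene lists past the threshold numbered 12 for TTNPB, 1 for AGN193109 and 7 for TTNPB against AGN193109. With an estimated correlation they were 2, 1 and 1, with fry 4, 1 and 5, and for AGN193109 they were 2 in clutch D and 0 in clutch E. With the term for the group of clutch D libraries they were 12, 3 and 11 (added: the early zygotic and ribosomal lists for AGN193109, and the ventral and BMP, neural plate, WNT and ribosomal lists for TTNPB against AGN193109). With the lists enlarged by gene number they were 12, 4 and 7, and 4, 1 and 4 with an estimated correlation. The lists that this enlargement brought past the threshold for AGN193109 were the retinoid list (adjusted p = 1.84e-04, with the second *cyp26a1* record as a member), the early zygotic list (0.0239) and the ribosomal protein list (0.0303). For TTNPB against vehicle with an estimated correlation they were the retinoid (0.0226) and FGF (0.0368) lists. Of the records changed by TTNPB, 90.6% were higher under quantile normalization, the lower of both scalings, and 92.9% without the 10 most abundant records, so neither scaling nor dominant records removed the excess of rises.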

Other observations

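Beyond the lists and the genes named by rule, some further records raised by TTNPB are given here. They were chosen after their values were seen and stand for no tested group. The Meis3 homeoprotein, a hox cofactor, rose by log2 1.77 ± 0.16, nocA-like zinc finger 1 by 1.99 ± 0.20, an NK6-related transcription factor by 1.72 ± 0.21 and the Dachshund-like record DAWG by 1.59 ± 0.13 (SE, 8 libraries each, limma adjusted p at most 1.12e-05). *kremen2*, a WNT co-receptor modulator, rose by 1.48 ± 0.15, and the frizzled genes *fzd6* and frizzled 4 by 0.89 ± 0.15 and 0.87 ± 0.15. Kielin rose by 1.17 ± 0.13 and twisted gastrulation by 1.11 ± 0.20.

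The hypothesis that AGN193109 lowers the genes that TTNPB raises was tested with a rule written before its result. Of the 154 records raised by TTNPB 95 (61.7%) were lower with AGN193109 than with vehicle, against 56.1% of all records. Because both comparisons share the vehicle libraries, these were divided, the raised records chosen against one part and AGN193109 compared with the other. In 36 of 36 divisions the median AGN193109 change of the chosen records lay below the median of all records, with a median difference of -0.18 (-0.22 to -0.11). Without AGN193109 replicate 4E the same held in 36 of 36 divisions, with a smaller median difference of -0.12 (-0.18 to -0.08), and the median share of chosen records that were lower went from 74.9% to 58.2%. Without that library the median of all records was above 0 in every division (0.0255 to 0.100). The median of the chosen records lay between -0.0852 and -0.0211 there. The 56.1% above, from the fit with all libraries, is therefore no background for the 58.2%. Part of the difference of -0.12 is that upward shift of all records, which records low with vehicle would show less on this scale. How many of the chosen records this concerns was not counted. The 36 of 36 divisions without replicate 4E argue against that library as the whole source of the difference, but not against a part of it. They do not settle how far AGN193109 itself lowered the chosen records. The divisions share libraries and are not independent. A receptor activity present without added agonist may hold up part of the TTNPB-responsive set, as a hypothesis found and tested on the same data. Whether such activity needs a ligand of the embryo was not tested.

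Without AGN193109 replicate 4E the 16 records past the threshold for AGN193109 included both *cyp26a1* records (-1.86 ± 0.14 and -1.41 ± 0.11), *sult6b1.5* (0.76 ± 0.12), *nudt4* (0.54 ± 0.10), glycolipid transfer protein-A (0.50 ± 0.09), F-box protein 11 (0.37 ± 0.07) and *znf106* (0.27 ± 0.05).

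Within clutch D, vehicle replicate 3D, TTNPB replicate 4D and AGN193109 replicates 2D and 4D stood together, although their replicate numbers differ in part. Their second principal component ran from 4.77 to 7.90 (other clutch D libraries 24.6 to 30.5), their 10 most abundant records took 44.1% to 47.9% of FPKM (others 57.7% to 62.8%), and their deviations correlated at 0.0849 to 0.168 between exposures. The source of this grouping, which is uneven over the exposures, was not tested.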
